A study of Arabidopsis thaliana with 6 samples.

How the data were processed

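Per the labels, total RNA was extracted from whole seedlings with a modified Trizol method and a silica column, and 15 µg of biotinylated cRNA was hybridised to each ATH1 array. The deposited values are intensities of probe sets on a linear scale, and per the labels the authors obtained them from the array images with GCOS 1.1 at a target intensity of 500. In the values used, the mean of each array trimmed by 2% at either end was 500.04, as that scaling gives. Per the labels the authors went on to divide by a percentile of each array and by the wild type of the same experiment in GeneSpring 7.0, but the values used here are intensities before that division, and wild-type arrays were not used here. The tests had been designed for ratios to the wild type. With intensities of the mutants alone, the comparisons of each mutant with the wild type, the genes shared by both mutants and their correlation were not run, and bzr1-1D was compared with det2 on the intensities. For want of a genome the promoter motifs of called genes were not examined, and 0 genes were called.

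Intensities were raised by 50 and log2-transformed without further scaling. Of 22810 probe sets, 64 Affymetrix controls were left out and 22746 were tested, with no filter on dim probe sets. The platform annotation used paired 13513 of the 22746 with 1 gene, 503 with several and 8730 with none, and probe sets of several genes are not named. Through the gene identifier, 13436 were matched to a locus tag of the TAIR10.1 gene table, covering 13286 genes; the table was used for names and for gene order alone. A gene with several probe sets was represented by the one whose name ends in _at without s or x, then by the first by name.

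The difference between bzr1-1D and det2 was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with the experiment as a block and Benjamini-Hochberg adjustment over all 22746 probe sets. The labels state that the genotypes were grown alongside each other in numbered experiments, so same-numbered arrays are paired. The correlation across probe sets of their deviations from the genotype means was 0.39 in experiment 1, 0.08 in experiment 2 and 0.37 in experiment 3. Between arrays of different experiments it ran from -0.37 to 0.11. The highest of these, bzr1-1D of experiment 3 with det2 of experiment 2, exceeded the value of experiment 2. The pairing in experiment 2 thus rests on the labels. The labels call the arrays biological replicates. With the block, p-values measure how the difference between genotypes within an experiment varies over the 3 experiments. Gene lists of at least 3 measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and list members were also adjusted over the list alone.

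The design, the 24 gene lists with 271 genes, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among single-gene probe sets with an adjusted p under 0.05 and 1 direction in 3 experiments, BZR1 and DET2, and up to 4 members of each list, those that did not pass only as values. No probe set met its first part, so genes with an unadjusted p under 0.01, 1 direction in 3 experiments and a mean intensity of at least 100 in the higher genotype were named instead, a rule chosen after the values were seen. The offset of 50 was chosen before any comparison was computed, and several of the alternatives were explored before the analyses took their final form. Also chosen after the data were seen were 20 gene families defined by their symbols, a list of 39 low-oxygen genes, the scan of 200-gene windows moved by 50 genes with 10000 permutations, and the alternatives without an offset (floor 0.1), with an offset of 16, with a mean intensity of at least 100 and with eBayes trend.

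A symbol rule that had taken peptide deformylases for defensins was corrected after values were seen. The computations were tested on simulated data with the measured means and experiment effects, in which 200 of 22746 probe sets were changed. The spread of each probe set was not its own but drawn from the distribution that limma fitted over all probe sets. It was the same in every experiment. Each of the 200 was changed by the same amount in every experiment, and noise was independent between probe sets. For bzr1-1D against det2, 2% of 50 probe sets with a log2 difference of 1, 76% with 2, 92% with 3 and 98% with 4 were recovered, with 3 false calls, and the median estimate was between 0.963 and 1.00 of the true difference. Of 20 lists of 10 members, 5 of 5 shifted lists were recovered, with 1 false call among the lists that were not shifted. Every member of a shifted list was moved by a log2 difference of 1. The planned lists that were tested had only 4 to 6 members, so this says little about them. Figures were drawn with matplotlib 3.10.9.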

Results

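Transcript levels were measured in whole seedlings of 2 Arabidopsis thaliana brassinosteroid mutants in the Columbia-0 background. The bzr1-1D mutant carries a dominant gain-of-function allele of BZR1, a transcription factor that acts at the end of the brassinosteroid signalling pathway, and det2 lacks the steroid reductase of brassinosteroid synthesis, so the pair sets constant hormone output against hormone shortage. Seedlings had grown for 5 days in gently shaken liquid culture under constant light at 22 °C and had then received ethanol alone, as the mock treatment, for 3 hours. Each genotype had 3 arrays, 1 from each of 3 experiments run in different weeks, and same-numbered arrays came from the same experiment. The arrays were 1-colour Affymetrix ATH1 arrays with intensities for 22746 probe sets that are not controls. Median intensity lay between 212.55 and 221.15 over the 6 arrays, and between 19.6% and 21.5% of the probe sets were below an intensity of 50. The ratio of the 3′ to the 5′ GAPDH probe set, a sign of how complete the labelled RNA is, followed the experiment and not the genotype. It was 0.757 in bzr1-1D and 0.800 in det2 in experiment 1, 0.463 and 0.461 in experiment 2, and 0.496 and 0.474 in experiment 3. The same ratio for actin was higher in det2 in each experiment. For actin it was 1.24 in bzr1-1D and 1.274 in det2 in experiment 1. In experiments 2 and 3 it was 1.219 and 1.25 in bzr1-1D and 1.38 and 1.325 in det2. The number of arrays, 3 per genotype, limits the precision of every value.

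The question the mutants pose is which genes differ in level between seedlings with BZR1 constantly active and seedlings short of brassinosteroid. ECS1 (AT1G31580) had the lowest difference, bzr1-1D minus det2, of the genes described here on the scale of log2 of intensity plus 50, though with no offset it was -3.99 against -3.92 for PDF1.2A. It encodes a protein associated with the cell wall, and its intensity was 462 ± 345 (SD, n = 3) in bzr1-1D and 6481 ± 2308 (SD, n = 3) in det2, and it was lower in bzr1-1D in each of the 3 experiments. AT1G52100, a lectin of the jacalin family, lay at the other end, with 1885 ± 339 (SD, n = 3) in bzr1-1D and 330.9 ± 265 (SD, n = 3) in det2. Neither gap passed the test over all probe sets. With limma, the experiment as a block and Benjamini-Hochberg adjustment, 0 of the 22746 probe sets had an adjusted p under 0.05, and the smallest adjusted p was 0.565. The SD of log2 differences over all probe sets was 0.35 in experiment 1, 0.592 in experiment 2 and 0.469 in experiment 3. The smallest adjusted p by limma was 0.059 without experiment 1, 0.818 without experiment 2 and 0.973 without experiment 3. No probe set passed in any of these fits. With all 3 experiments, 1556 probe sets had an unadjusted p under 0.05, 624 higher and 932 lower in bzr1-1D, where chance alone gives 1137. Of all probe sets, 28.0% kept 1 direction in the 3 experiments, where chance gives 25%. The pseudogene AT1G20390, with 68.1 ± 5.45 (SD, n = 3) in bzr1-1D and 436 ± 31.3 (SD, n = 3) in det2, was the 1 probe set past the threshold by limma without the block (adjusted p = 0.032) and with the experiment as a random effect (adjusted p = 0.0155). In data simulated on these arrays for this comparison, 22746 probe sets in all, the same test recovered 76% of the genes given a log2 difference of 2 and 2% of those given a log2 difference of 1, with 3 false calls.

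No gene met the rule set for naming genes, so those described from here to the chromosome counts, ECS1, AT1G52100 and AT1G20390 included, were chosen after their values were seen. They had an unadjusted p under 0.01 by limma, 1 direction in all 3 experiments and a mean intensity of at least 100 in the higher genotype. By these criteria 34 genes were higher and 91 lower in bzr1-1D, and the 12 with the largest log2 difference on each side are shown in the plot of single experiments. Their adjusted p (limma, Benjamini-Hochberg) ran from 0.565 to 0.701, so none is called. Differences are bzr1-1D minus det2, on the scale of log2 of intensity plus 50, which understates the difference of dim genes.

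**Figure D1:**
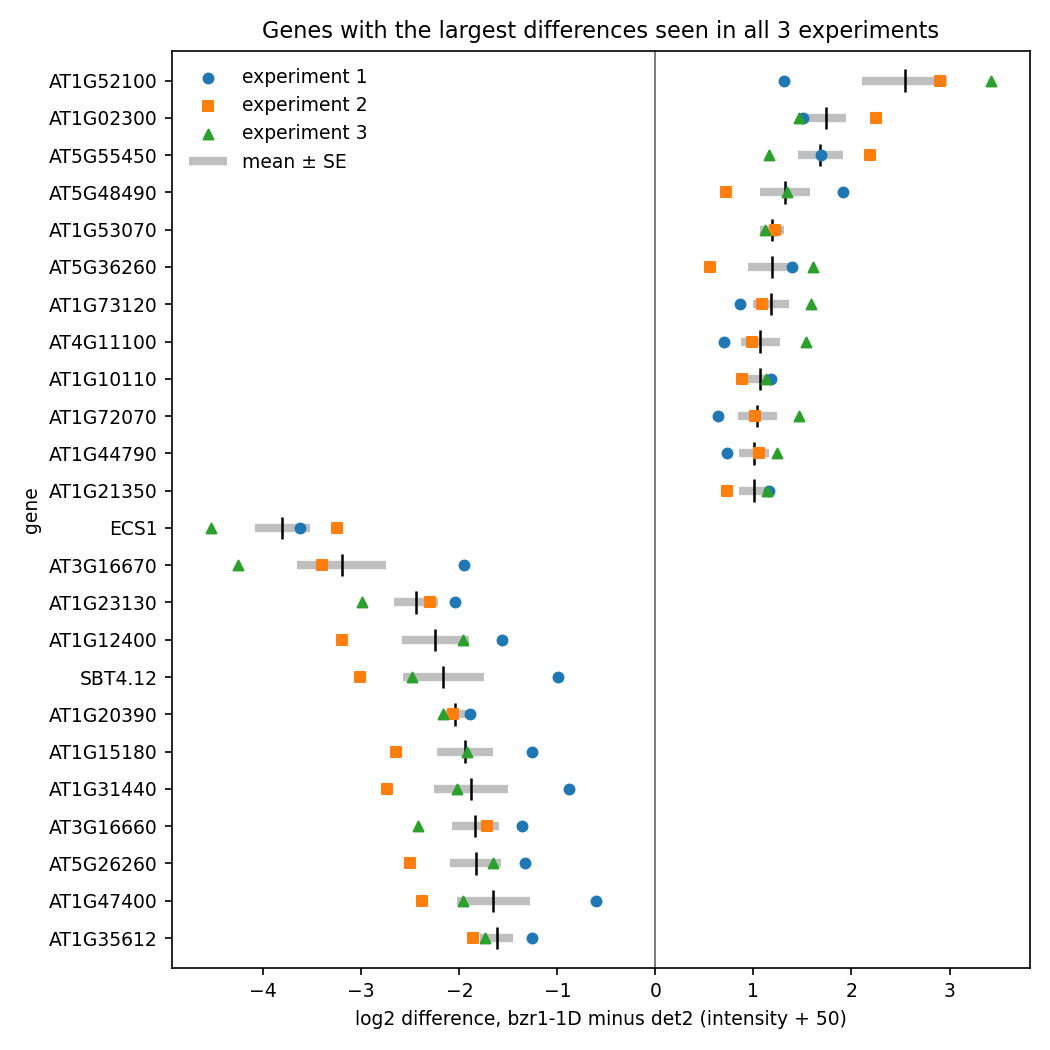
Log2 difference, bzr1-1D minus det2, of log2(intensity + 50) on the x axis for 24 genes on the y axis, with 1 marker per experiment, a black line for the mean of 3 experiments and a grey bar for ± 1 SE. ECS1 is the lowest with a mean of -3.80, AT1G52100 is the highest with a mean of 2.54, and all 3 markers of each gene lie on 1 side of 0.

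Of the genes that were higher in bzr1-1D, AT1G02300, a cathepsin B-like cysteine protease, stood at 866 ± 231 (SD, n = 3) in bzr1-1D and 231 ± 108 (SD, n = 3) in det2, a log2 difference of 1.74 ± 0.21 (SE). The lipid transfer proteins AT5G55450 and AT5G48490 had log2 differences of 1.68 ± 0.23 (SE) and 1.33 ± 0.26 (SE). AT1G53070, a legume-type lectin, was the most even of them, with 1.22 in experiments 1 and 2 and 1.11 in experiment 3. The aspartyl protease AT5G36260 was at 137 ± 26.1 (SD, n = 3) in bzr1-1D and 33.5 ± 21.0 (SD, n = 3) in det2, a log2 difference of 1.19 that was 1.70 with an offset of 16 and 2.20 with none. AT1G73120 (1.18), AT4G11100 (1.07), AT1G10110 (1.06), AT1G72070 (1.04), AT1G44790 (1.01) and AT1G21350 (1.01) made up the rest of the 12, with the log2 difference in brackets.

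The 12 genes that were lower in bzr1-1D, taken from 91 against 34, had wider gaps rank for rank. AT1G52100 (2.54) still exceeded all of them but ECS1 and AT3G16670 in size. AT3G16670 and AT3G16660, members of the pollen Ole e 1 family whose locus numbers follow each other on chromosome 3, had log2 differences of -3.20 ± 0.46 (SE) and -1.84 ± 0.24 (SE). AT3G16670 was at 233 ± 89.0 (SD, n = 3) in bzr1-1D and 3281 ± 2314 (SD, n = 3) in det2. AT1G23130, of the Bet v 1 family, was at 429 ± 131 (SD, n = 3) against 2772 ± 1494 (SD, n = 3). The subtilase SBT4.12 had a log2 difference of -2.16 ± 0.41 (SE) and the MATE transporter AT1G15180 one of -1.94 ± 0.29 (SE). AT1G47400, a short peptide induced by iron shortage, stood at 708 ± 282 (SD, n = 3) in bzr1-1D and 2896 ± 1949 (SD, n = 3) in det2, and its gap was smallest in experiment 1 (-0.61) and largest in experiment 2 (-2.38). The others were AT1G12400 (-2.24), AT1G20390 (-2.04), AT1G31440 (-1.88), AT5G26260 (-1.83) and the pseudogene AT1G35612 (-1.62). AT1G35612 had a mean below the offset of 50 in bzr1-1D and 163.8 ± 77.9 (SD, n = 3) in det2, and its log2 difference was -2.43 with an offset of 16 and -3.55 with none. Of the 12 genes on each side, 8 that were higher and 8 that were lower in bzr1-1D lie on chromosome 1.

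Genes with a small unadjusted p were unevenly spread over the chromosomes, though none passed adjustment. Among the genes placed in order along the 5 chromosomes, 158 of 13217 had an unadjusted p under 0.01 by limma, where chance gives 132, and 70 of these were on chromosome 1, against 16 on chromosome 2, 22 on chromosome 3, 18 on chromosome 4 and 32 on chromosome 5. As shares of the genes placed, that was 2.05% on chromosome 1 and between 0.738% and 1.07% on the others. On chromosome 1, 55 of the 70 were lower in bzr1-1D. Counted in windows of 200 neighbouring genes, the fullest window held 13 such genes, from AT1G20890 to AT1G24510, and chance placement gave a fullest window of 7 in the median of 10000 permutations (permutation p = 5e-04). Windows above the 95th percentile of the permutations, 9 genes, numbered 4 and lay in 2 pieces of chromosome 1 between AT1G20890 and AT1G35663, which hold ECS1, AT1G23130, AT1G31440, AT1G35612 and AT1G21350 of the genes described above. Without experiment 1 the permutation p of the fullest window was 0.47 and without experiment 3 it was 0.045, in both cases with the fullest window elsewhere on chromosome 1 and holding 0 genes of these pieces. The first of these windows, AT1G71695 to AT1G75460, spans the BZR1 locus. Without experiment 2 the permutation p of the fullest window was 0.036, with 150 of the 200 genes of the window on them. This scan was chosen after the leading genes were seen.

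**Figure D2:**
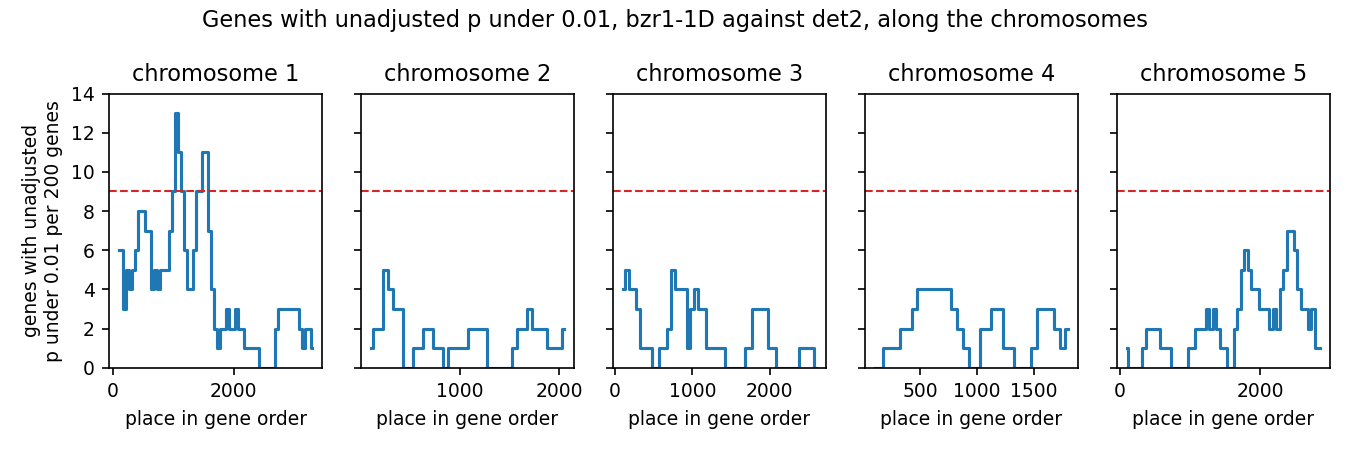
Number of genes with an unadjusted p under 0.01 (limma) per window of 200 neighbouring genes on the y axis, against the window's middle place in gene order on the x axis, for each of the 5 chromosomes. The dashed line is at 9, the 95th percentile of the fullest window in 10000 permutations; windows on chromosome 1 reach 13 and no window of the others passes the line.

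The gene lists fixed for brassinosteroid action and seedling growth were measured only in part, since 38 of their 271 genes had a named single-gene probe set. Of the 38 genes, 25 were higher and 13 lower in bzr1-1D, 3 had an unadjusted p under 0.05 by limma, 0 passed over all probe sets and 2 passed when adjusted over the list alone. BZR1 and DET2, the mutated genes, had no named probe set and are not analysed here. The lists of brassinosteroid synthesis, sterol synthesis, brassinosteroid inactivation, primary and secondary wall cellulose synthesis with xylem, ethylene, heat shock, salicylate defence, and iron and nitrate nutrition had 0 named members.

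Neither list of cell wall loosening passed its set test. Of 6 expansins, which loosen the wall in growing cells, 5 were higher and 1 lower in bzr1-1D and 0 had an unadjusted p under 0.05 by limma. EXPA4 stood at 1358 ± 319 (SD, n = 3) in bzr1-1D and 1178 ± 345 (SD, n = 3) in det2, and EXPB3 had a log2 difference of 0.24 ± 0.31 (SE). Of 6 xyloglucan endotransglucosylases, which cut and rejoin wall xyloglucan, 5 were higher and 1 lower. The family taken by gene symbol, chosen after the data were seen, had 10 genes. Of these 5 were higher and 5 lower, with a median log2 difference of -0.0091. XTH16 had 814 ± 197 (SD, n = 3) in bzr1-1D and 506 ± 336 (SD, n = 3) in det2, with 1 direction in all 3 experiments (limma, unadjusted p = 0.0399, adjusted p = 0.712 over all probe sets and 0.239 adjusted over the list alone). XTH18 had a log2 difference of 0.93 ± 0.58 (SE), with -0.42 in experiment 1 and 2.55 in experiment 2. XTH33 and XTH27 had 0.42 ± 0.23 (SE) and -0.25 ± 0.12 (SE). By camera with a preset correlation of 0.01, the adjusted p (Benjamini-Hochberg over 4 lists) was 0.291 for either list, and 0.576 with an estimated correlation.

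Of the hormone and stress lists a set test was run on auxin response and on cold and abscisic acid, and neither passed. Of 5 auxin response genes 3 were higher and 2 lower, with IAA20 at a log2 difference of 0.30 ± 0.15 (SE), which was 0.52 with an offset of 16 and 0.82 with none, and GH3.5 at -0.30 ± 0.28 (SE), which was -0.68 without experiment 2 and -0.0338 without experiment 3, and camera gave an adjusted p of 0.311. Of 4 cold and abscisic acid genes 3 were higher and 1 lower, with COR47 at 0.18 ± 0.14 (SE) and LTI30 at 0.56 ± 0.45 (SE), and camera gave an adjusted p of 0.291. With an estimated correlation the adjusted p was 0.576 for both lists. The gibberellin receptors GID1A and GID1B had log2 differences of -0.19 ± 0.13 (SE) and 0.39 ± 0.17 (SE). The brassinosteroid receptor homologue BRL1 and the BES1 partner BIM1 had 0.07 ± 0.15 (SE), which was 0.12 with no offset, and -0.03 ± 0.16 (SE). The defensin PDF1.2A, a marker of jasmonate and ethylene defence, was at 32.2 ± 14.1 (SD, n = 3) in bzr1-1D and 898 ± 978 (SD, n = 3) in det2. It was lower in bzr1-1D in all 3 experiments and passed when adjusted over the list alone, a list of 2 measured genes (limma, adjusted p = 0.0238), but not over all probe sets (adjusted p = 0.701). Over the list alone its limma adjusted p was 0.137 without experiment 3. HRA1, the 1 measured gene of the low oxygen list, differed far more between experiments than between genotypes, with 94 and 44.7 in experiment 1 against 2900.2 and 3534 in experiment 3 for bzr1-1D and det2.

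**Figure D3:**
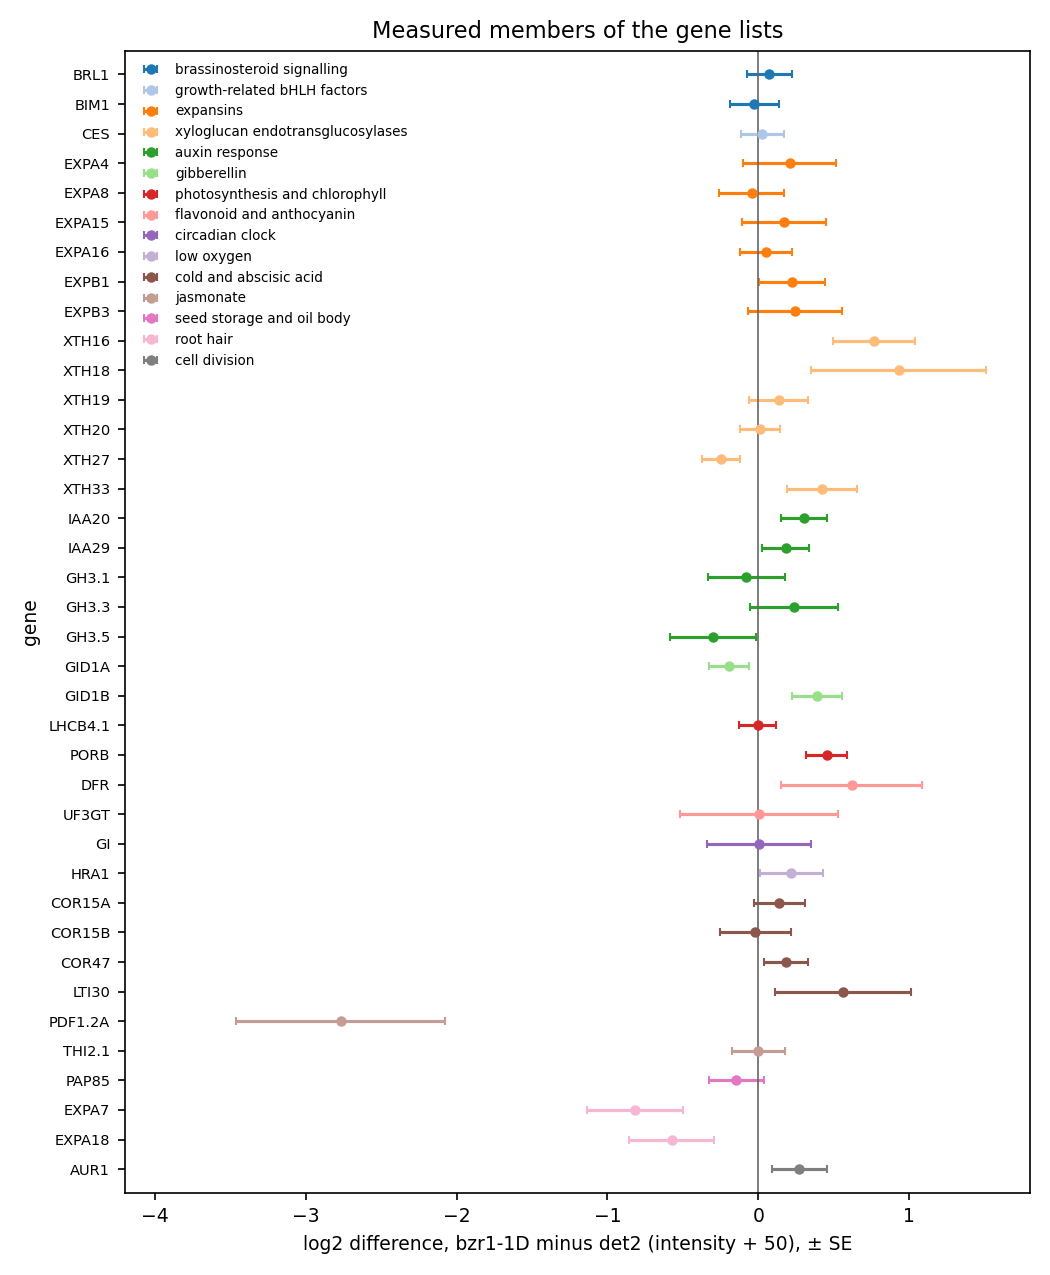
Log2 difference, bzr1-1D minus det2, of log2(intensity + 50) on the x axis for the 38 measured members of the gene lists on the y axis, as the mean of 3 experiments ± SE, coloured by list. PDF1.2A lies lowest at -2.77 and XTH18 highest at 0.93.

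Among markers of tissue and stage, PORB, a protochlorophyllide reductase of chlorophyll synthesis, was at 8094 ± 1167 (SD, n = 3) in bzr1-1D and 5872 ± 488 (SD, n = 3) in det2, was higher in bzr1-1D in all 3 experiments, and passed when adjusted over the list alone, a list of 2 measured genes (limma, adjusted p = 0.0465), but not over all probe sets (adjusted p = 0.701). Over the list alone its limma adjusted p was 0.145, 0.201 and 0.0969 without experiments 1, 2 and 3, and 0.132 with no offset. The root hair expansins EXPA7 and EXPA18 were both lower in bzr1-1D in all 3 experiments, with log2 differences of -0.82 ± 0.32 (SE) and -0.57 ± 0.28 (SE), and neither had an unadjusted p under 0.05 by limma. Without experiment 2 they were -0.37 and -0.20. AUR1, an Aurora kinase of dividing cells, had a log2 difference of 0.27 ± 0.18 (SE) and the seed storage protein PAP85 one of -0.15 ± 0.18 (SE), which was -0.24 with no offset. DFR, of anthocyanin synthesis, had 0.62 ± 0.47 (SE), with -0.76 in experiment 2 and 1.31 in experiment 3. The bHLH factor CES and the clock gene GI, each the 1 measured member of its list, had log2 differences of 0.03 ± 0.14 (SE) and 0.00 ± 0.35 (SE).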

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

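Planned before the data were examined were centring each array, quantile normalization, robust eBayes, array weights, a fold minimum, leaving out probe sets ending in _s_at or _x_at, fits without the replicate block or with it as a random effect, leaving out each experiment, and for lists an estimated correlation. The other offsets, a mean intensity of at least 100, eBayes trend, lists without the block, members adjusted over the list alone without the block, with it as a random effect or with no offset, and all alternatives for gene families and the chromosome 1 share were chosen after seeing the data. The count of probe sets past an adjusted p of 0.05 by limma was 0 with the replicate block, against 1556 at an unadjusted p under 0.05, and it was 1 with no replicate block and 1 with the replicate block as a random effect. That probe set was AT1G20390 (adjusted p = 0.032 and 0.0155), and the cause was not tested. The count was 0 in the other alternatives, from 0 to 0 when an experiment was left out. At an unadjusted p under 0.05 it was 213 with the fold minimum, which by construction removes small differences, and ran from 768 without experiment 3 to 2222 without experiment 1. Of the 4 planned lists, 0 passed camera, and from 0 to 1 when an experiment was left out. The 1 was the expansins without experiment 2 (median log2 difference 0.46, adjusted p = 0.0229, up to 0.576 over the alternatives). The block changed no other call over all probe sets, over a list alone or of a planned list, but the plastid photosystem and cytochrome family, past camera with it (adjusted p = 0.0167), was lost with no replicate block (0.178) and with an estimated correlation (adjusted p = 0.953). List medians changed sign when an experiment was left out for expansins (-0.15 to 0.46), auxin response (-0.0338 to 0.167), cold and abscisic acid (-0.0475 to 0.280) and plastid ribosomal proteins (-0.215 to 0.0363). So did 6 of the 46 genes followed through the alternatives, BIM1 (-0.195 to 0.0593), BRL1 (-0.0537 to 0.178), LTI30 (-0.0855 to 1.02), EXPA4 (-0.11 to 0.62), EXPB3 (-0.18 to 0.56) and PAP85 (-0.344 to 0.0115), and the cause was not tested. CES, GI and the single plastid genes named were not followed. Leaving out 1 experiment moved 19 of the 22 list members that were followed by over 1.5 times. Adjusted over the list alone, 2 members passed with all experiments, from 0 without experiment 3 to 3 without experiment 2, and 1 passed with no offset. The share of differing genes on the crowded pieces of chromosome 1 ran from 6.85% without experiment 1 to 23.1% without experiment 3, against 16.5% with all. Comparisons with the wild type, genes shared by both mutants, their correlation, promoter motifs and ratios limited to between 0.1 and 10 were not run. Between 19.6% and 21.5% of probe sets lay below an intensity of 50, where signal over background limits what can be measured.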

Other observations

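Most tests reported here were chosen only after the result was seen: the gene families, the chromosome scans and the direction of the genes, the single-array, all-gene shift and low-oxygen tests, the tests on experiment 1, which replaced 1 written beforehand, and the splits. Genes encoded in the plastid lay slightly lower in bzr1-1D than in det2, 41 of 51 over 3 families. Of 26 photosystem and cytochrome genes 22 were lower, with a median log2 difference of -0.17. Only 3 of the 26 had an unadjusted p under 0.05 by limma, and 0 passed adjustment over all probe sets or over the family alone. psbA, which encodes the D1 protein of photosystem II, had -0.81 ± 0.27 (SE), psbE -0.32 ± 0.12 (SE) and psbN -0.41 ± 0.15 (SE), each lower in all 3 experiments. By camera with the preset correlation the adjusted p of this family (Benjamini-Hochberg over 20 families) was 0.0167, but adjusted p = 0.953 with an estimated correlation, 0.235 without experiment 1, 0.285 without experiment 2, 0.178 with no replicate block and 0.132 with no offset. It was 0.00299 without experiment 3, 0.0174 with centred arrays and 0.0196 after quantile normalization. Of 10 NDH genes 8 were lower (camera adjusted p = 0.224), with ndhE at -0.51 ± 0.15 (SE) and ndhH at -0.48 ± 0.15 (SE). Of the 10, 2 had an unadjusted p under 0.05 by limma and 0 passed either adjustment. Of 15 plastid ribosomal protein genes 11 were lower (camera adjusted p = 0.775), a family whose adjusted p was 0.00299 without experiment 3 and whose median turned to 0.04 without experiment 2. The camera adjusted p of the other families was between 0.775 and 0.966.

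Genes with an unadjusted p under 0.01 by limma, none of which passed adjustment, crowded on part of chromosome 1. There they were 26 of 500 genes (5.2%) against 1.04% elsewhere, and BZR1 lies outside these pieces. The pieces were picked as the windows fullest of these same genes, so that gap was largely fixed by the selection. The fullest window had a permutation p of 5e-04, but that does not settle chance placement. The permutations treat neighbouring genes as independent, and the scan was chosen after the leading genes were seen. Other assignments of genotypes within experiments gave a permutation p of 0.0759, 0.0809 and 0.45. With the real assignment it was 0.47 without experiment 1, where the fullest window spans the BZR1 locus. Noise of dim probe sets was examined with a scan of the 6168 genes of mean intensity 200 or more alone. It was run in place of an odds ratio that the selection of the pieces had largely fixed. Its fullest window, AT1G16740 to AT1G24140, held 13 genes with an unadjusted p under 0.01 by limma. The 95th percentile of the permutations was 10 (permutation p = 0.001). Within the limits of such permutations, crowding on chromosome 1 was thus also found with the dimmer genes left out. The window had 93 of its 200 genes on the pieces and missed the bar set for lying on them. The pieces hold only 214 such genes, in 2 parts, so the test could not decide. Dim noise stays open for the crowding on the pieces. Spread between arrays stays open: under 2 of the 3 other assignments of genotypes within experiments the fullest window held 16% (4 of 25 genes, permutation p = 0.0759) and 9.30% (4 of 43, permutation p = 0.45) of the genes under that p, above the real 8.23%, which met what had been written beforehand for this cause, and a condition on the permutation p was added after this was seen. A segment from another accession in the bzr1-1D line is a candidate explanation, as a hypothesis, and it stays open because the odds ratio of being lower in bzr1-1D, on the pieces against elsewhere, was 3.55 with a 95% interval of 0.99 to 19.5.

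Genes induced by low oxygen were high in experiment 3 in both genotypes, and 4 probe sets passed limma for that experiment (Benjamini-Hochberg adjusted p = 0.0261 for HRA1 and AT1G33055, 0.0287 for AT5G26200 and AT5G42200), against 1383 at an unadjusted p under 0.05. Of the 23 measured genes of a low-oxygen list written after the leading genes were seen, the 10 outside the 40 leading ones had median rises of 0.55 in bzr1-1D and 1.43 in det2, at least percentile 99.99 of 10000 matched random lists in both. That argues against a fault of a single array, although 0.55 had missed a first criterion of a rise over 1 in both genotypes. A shift of all genes, which would move the matched lists too, is argued against by the same percentile, in place of a bound on the median over all probe sets that was met (at most 0.0224) but fixed by the scaling of the arrays. Less oxygen in the flasks of experiment 3 may account for it, as a hypothesis, resting on those same 10 genes and on percentile 99.99.

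The arrays of experiment 1 resembled each other across genotypes (r = 0.979 across probe sets, against 0.938 to 0.974 within genotypes), and of 313 probe sets chosen for their difference in experiments 2 and 3, 60.1% (95% interval 54.4 to 65.5) kept their direction in experiment 1, with a median of 0.0499 of their difference, against 84.7% of 59 (0.889) and 81.0% of 58 (0.756) for the same test on experiments 2 and 3. A swapped label in experiment 1, which would put that share below 50%, is argued against by its interval, although 60.1% had missed the bound of 75% written beforehand for 1 RNA or a swap together. One RNA or one genotype on both arrays is argued against only by 43 of those probe sets, which differed by over 1 on the log2 scale in experiment 1. Of these, 79.1% (95% interval 64 to 90) had the direction of experiments 2 and 3. The same test on experiments 2 and 3 gave 91.9%, which is no separate benchmark, since the same 34 probe sets count as in direction in all 3 tests. They were 34 of the 313 chosen for experiment 1, against 34 of 59 and 34 of 58 for experiments 2 and 3. Most of the 313 thus did not reach such a difference in experiment 1. Probe sets are not independent, so both intervals are too narrow, and the small median of 0.0499 leaves partly mixed RNA open, which was not tested. A shared week does not by itself account for the resemblance, since same-numbered arrays shared an experiment in all 3. Across genotypes r was 0.941 in experiment 2 and 0.963 in experiment 3. A condition of growth or hybridisation particular to experiment 1 stays a hypothesis. Of 13 bright spike-in probe sets, 92.3% were highest in experiment 1 in both genotypes, where chance gives 11.1%. Spike-in controls are added at hybridisation, and their probe sets on 1 array are not independent of each other. They therefore bear on hybridisation alone, and not on growth or on whether seedling RNA was mixed.

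The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. The count of probe sets past an adjusted p of 0.05 by limma was 0 for the genotypes and at most 0 in the other splits, so all 10 were as large. At an unadjusted p under 0.05 the genotypes gave 1556 and 3 of the 10 splits gave at least as many. The highest other, 2298, comes from 2 splits that part 1 pair and give the same fit with the block, resting on that pair alone, and among the 4 splits that part all 3 pairs the highest other was 1364.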
